A study of Mus musculus with 574 samples.

How the data were processed

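The samples were 550 single cells and 24 pools of 100 cells from the developing ventral midbrain of C57BL/6 mice heterozygous for Lmx1a-EGFP, with 137 cells at E10.5, 90 at E11.5, 178 (63 with titles starting with C and 115 with F) at E12.5 and 145 at E13.5. Libraries were made with Smart-seq2 and Nextera XT kits and sequenced on a HiSeq 2000, per the labels. The submitters' processing notes name the aligner STAR 2.3.0 and the genome build mm10. The read counter, the annotation and any filters are not given in the sources used here. The deposited table of pools holds RPKM (reads per kilobase of transcript and M reads) of 23706 genes. The deposited table of single cells holds log2 values of 25489 genes, which the authors formed as log2(RPKM + 0.001), as its lowest value shows, and these were turned back into RPKM. Each table also has a line for the EGFP reporter. No pair of columns was identical, and Pearson correlations across genes between pools of the same group lay between 0.934 and 0.960.

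The tables hold no read counts, so the depth of a library was estimated from the step between its lowest values. Only a median of 31.2% of low values in pools and 29.1% in cells lay within 0.05 of a whole number of reads, against 10% by chance, so these depths are rough. They were 1.30 to 3.67 M reads per pool and 0.401 to 7.47 M per cell. An RPKM of 10 for a transcript of 2 kb corresponds to about 55.2 reads in a median pool and 27.2 in a median cell. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

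Pools were grouped by stage and GFP class as the labels give them, with 6 pools in each of 4 groups. Genes with an RPKM of at least 1 in at least 6 pools were tested, 15871 in all. Values of log2(RPKM + 1) were fitted with limma 3.58.1 in R 4.3.3, with the 4 group means in 1 model and moderated variances with a trend, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The contrasts were GFP positive against GFP negative at each stage, E13.5 against E10.5 in each GFP class, and the difference between stages of the GFP difference. Values of groups are means and SD of RPKM, and log2 differences carry the standard error of the model. EGFP was compared by an exact permutation test. Overlaps of called genes were tested with Fisher's exact test.

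The 10 genes named in each direction of a comparison had the largest log2 differences among called genes with a mean RPKM of at least 10 in the higher group and no overlap between the 6 values of the groups. For the difference between stages the overlap condition was left out. Members of 23 gene lists, Lmx1a and the reporter were also reported. The 4 Y-linked genes were chosen after the values of Xist were seen. Lists were tested with camera from limma at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists of a contrast. The lists cover midbrain floor plate, dopamine neurons, the subthalamic lineage, caudal diencephalon and hypothalamus, neural progenitors, cell cycle, proneural genes and Notch ligands, pan-neuronal genes and GABAergic neurons. They also cover red nucleus and basal plate, cholinergic and motor neurons, serotonergic neurons, hindbrain, forebrain, roof plate and choroid plexus, red blood cells, endothelium, microglia and macrophages, mesenchyme and pericytes, early response and heat shock, hedgehog signalling, Wnt signalling and axon guidance. Slc18a3, Hoxa2, Hoxa3 and Hoxb4 in the pools, and Slc18a3, Hoxa3, Hoxb3, Hoxb4, Ttr and Notum in the cells, were not analysed here. Some listed or named genes are not reported here, although list results include them.

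The fit was tested on simulated data with known changes in the E13.5 GFP comparison. It recovered 41% of 100 genes changed 2-fold and 82% of 100 genes changed 4-fold, with 4 false calls among 134 (2.99%), and made 0 calls in the unchanged E10.5 comparison. A shifted pan-neuronal list was called (camera adjusted p = 2.71e-26), with 0 other lists. Genes were simulated independently of each other, whereas the estimated correlation in the data was 0.358 for the pan-neuronal list. The simulation therefore does not show how often correlated lists would be called falsely.

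Single cells were described without p-values, since the labels name no animal and each stage is 1 sample. A gene was taken as present at an RPKM of at least 10, and shares carry exact 95% Clopper-Pearson intervals. The dopamine gate required Th and Nr4a2 and the Barhl1 gate Barhl1 alone. The Barhl1 gate, its comparison with the dopamine gate and its alternatives replaced a planned gate after the data were seen. A gate on 1 gene is wider than one on 2 genes. For clustering, cells with at least 1000 genes at an RPKM of at least 1 and genes present at that level in at least 10 cells were kept. Values of log2(RPKM + 1) of the 2000 most variable genes, ranked within 20 bins of mean level, were reduced to 30 principal components. A graph of 15 neighbours was partitioned with the Leiden method at resolution 1 and seed 0 (scanpy 1.11.5, leidenalg 0.10.2). Clusters were named from the gene lists only, by the highest mean z score with at least 3 markers each found in at least 25% of cells. The score limit of 0.4 and the 25% limit were set after the data were seen. No doublet caller was run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Chromosomes and coordinates are from GENCODE M21.

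The comparisons, the limma and camera tests, gene lists, dopamine gate, clustering parameters and most alternatives were chosen before the data were examined. The plan did not list the exact test of EGFP, Fisher's test of overlaps, counts of genes without overlap or the adjustment over a list alone. The alternatives were pseudocounts of 0.1 and 10, no filter or a mean RPKM of at least 10, quantile normalization, upper quartile scaling, only the groups compared in the fit, other variance moderation, weights per pool, a fold change of at least 2, and each pool left out in turn. For cells they were presence at an RPKM of at least 1 or 30, cells with at least 4000 genes, E12.5 cells by title prefix, and other clustering parameters. Leaving out globin genes with rescaling was also added after the data were seen.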

Results

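Ventral midbrain cells were taken from mouse embryos (C57BL/6 background) heterozygous for an Lmx1a-EGFP reporter, in which cells that express the LIM homeobox gene Lmx1a also carry green fluorescent protein (GFP). RNA was sequenced with Smart-seq2, a full-length cDNA method for single cells and small pools. Of 550 single cells, 24.9% were taken at E10.5 (E for embryonic day), 16.4% at E11.5, 32.4% at E12.5 and 26.4% at E13.5. A further 24 libraries were pools of 100 cells, 6 each of GFP positive and GFP negative cells at E10.5 and at E13.5. The labels name no embryo or litter for either kind of library, so p-values between groups of pools measure only the spread between these pools, which may be technical, and each stage of single cells counts as 1 sample. The depth implied by the deposited values was 1.30 to 3.67 M reads per pool (median 2.76) and 0.401 to 7.47 M per cell (median 1.36). The series concerns how the lineages that give rise to midbrain dopamine neurons and to neurons of the subthalamic nucleus, a glutamatergic nucleus of the basal ganglia circuit, relate to each other.

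The reporter transcript and Lmx1a followed the sort. EGFP averaged 206 ± 20.96 RPKM in GFP positive pools at E10.5 (SD, n = 6) and 2.295 ± 2.21 in GFP negative pools, where single pools ranged from 0 to 5.82 (exact permutation test, two-sided p = 0.00216). At E13.5 EGFP averaged 60.6 ± 10.46 in GFP positive pools and was listed at 0 in all 6 GFP negative pools. Lmx1a, on chromosome 1 from 167689237 to 167848741 (plus strand, GRCm38), averaged 72.1 ± 7.95 and 1.55 ± 1.05 RPKM in GFP positive and negative pools at E10.5, and 56.6 ± 7.38 and 2.63 ± 1.22 at E13.5. These are log2 differences of 4.95 ± 0.27 (SE; adjusted p = 6.96e-13) and 4.07 ± 0.27 (adjusted p = 5.71e-11). From E10.5 to E13.5 EGFP fell in GFP positive pools (exact permutation test, two-sided p = 0.00216), while the stage difference of Lmx1a, -0.35 ± 0.27, did not pass the test (adjusted p = 0.29). All 3 exact p-values for EGFP are the smallest that 6 pools against 6 can give.

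**Figure D1:**
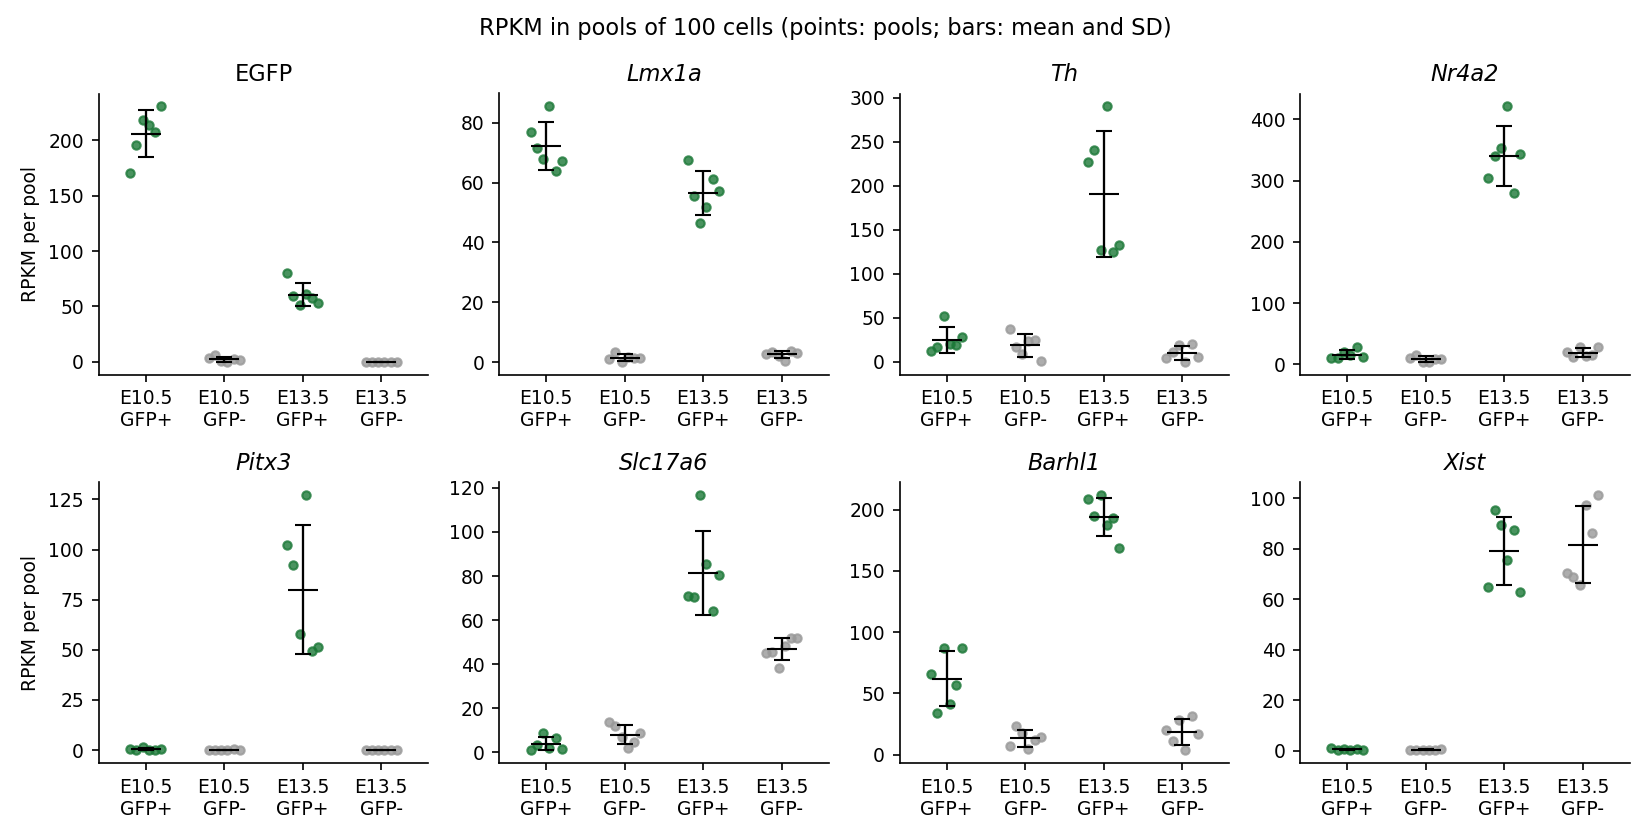
RPKM of the reporter transcript, 6 genes of the dopamine and subthalamic lineages and Xist in each pool of 100 cells (y axis, linear), by stage and GFP class (x axis), with the 6 pools of a group as points and bars for the mean and SD. Pitx3 averaged 79.98 RPKM in E13.5 GFP positive pools and was at most 0.454 in any E10.5 GFP negative pool, while Xist separated the stages in both GFP classes.

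At E10.5, GFP positive pools were compared with GFP negative pools to find the genes that accompany Lmx1a in the early ventral midbrain. Rspo2, which encodes an R-spondin that strengthens Wnt signalling, averaged 62.8 ± 10.2 RPKM in GFP positive and 0.184 ± 0.268 in GFP negative pools (SD, n = 6 each), a log2 difference of 5.76 ± 0.27 (SE; adjusted p = 6.53e-14). The Wnt ligand Wnt1 averaged 45.7 ± 9.04 against 0.0981 ± 0.240 RPKM (5.41 ± 0.39; adjusted p = 1.26e-10). Foxa2, a forkhead factor of the floor plate, was 124.7 ± 13.6 against 63.8 ± 18.4 (0.998 ± 0.19; adjusted p = 0.000484), and the floor plate morphogen Shh 65.9 ± 10.7 against 19.4 ± 8.02 (1.78 ± 0.29; adjusted p = 7.89e-05). All 12 members of the midbrain floor plate list were higher in GFP positive pools, also when adjusted over the list alone (camera adjusted p = 1.43e-27, and 4.76e-09 with an estimated correlation). The 10 named genes with the largest increases were Rspo2, Wnt1, Folr1 (5.20), which encodes a folate receptor, Lmx1a, the retinaldehyde dehydrogenase gene Aldh1a1, Ccdc3, Nav3, the serine protease gene Corin (4.23), the tachykinin precursor gene Tac1 and the Wnt antagonist gene Dkk2 (3.92). Aldh1a1 averaged 24.9 ± 7.54 RPKM in GFP positive pools and was listed at 0 in all 6 GFP negative pools.

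Genes of differentiating neurons were lower in E10.5 GFP positive pools. Tubb3, the neuronal beta tubulin, averaged 214 ± 37.9 RPKM in GFP positive and 928 ± 226 in GFP negative pools (log2 difference -2.09 ± 0.13, adjusted p = 1.74e-11). All 12 pan-neuronal genes were lower, also when adjusted over the list alone, with log2 differences of -3.38 for Stmn2 and -4.43 for the neurofilament gene Nefl (camera adjusted p = 8.25e-28, and 0.000207 with an estimated correlation). Isl1, a homeobox gene of motor neurons, averaged 0.278 ± 0.433 against 35.8 ± 14.3 RPKM (-4.77 ± 0.46; adjusted p = 2.24e-08), and all 3 tested cholinergic and motor neuron genes were lower (1.32e-07; 0.000207 with an estimated correlation). All 10 GABAergic genes were lower, among them Dlx1 (-4.52) and Gad2 (-2.81), with adjusted p = 3.99e-13, and 0.000207 with an estimated correlation. Of 7 red nucleus and basal plate genes 5 were lower, Nkx6-1 by a log2 difference of -2.22, and 6 when adjusted over the list alone (2.58e-07; 0.000472 with an estimated correlation). Of 13 proneural and Notch ligand genes 9 were lower, such as Neurog1 (-1.99), and 10 when adjusted over the list alone. That list's call (camera adjusted p = 2.13e-05) was lost with adjusted p = 0.0953 with an estimated correlation.

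Markers of the dopamine and subthalamic lineages were compared in the same way. The Bar-class homeobox gene Barhl1 averaged 62.01 ± 22.5 RPKM in GFP positive and 13.2 ± 6.77 in GFP negative pools (2.22 ± 0.37; adjusted p = 9.24e-05). Of the 5 subthalamic lineage genes 4 were higher, Barhl2 and Foxp2 included (2.64 and 1.22), with camera adjusted p = 0.000431, and 0.0466 with an estimated correlation. The vesicular glutamate transporter gene Slc17a6, also on the list, was lower only when adjusted over the list alone. Nr4a2, an orphan nuclear receptor gene of dopamine neurons, averaged 15.8 ± 7.02 against 8.73 ± 4.34 RPKM (0.82 ± 0.27; adjusted p = 0.0467). The call of Nr4a2 was lost in 8 of 12 fits without 1 pool and in 7 of 11 other settings (adjusted p up to 0.134). Th, the rate-limiting enzyme of dopamine synthesis, averaged 24.8 ± 14.6 against 18.9 ± 12.8 and did not pass the test (adjusted p = 0.545). Of the 14 dopamine neuron genes 4 were higher, Aldh1a1 included, and 3 lower, the same counts adjusted over the list alone, and the list was not called (0.454), its median being -0.06 and its mean 0.21.

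Transcripts of other cell types were also lower in E10.5 GFP positive than in GFP negative pools. The embryonic globin gene Hbb-y averaged 15.7 ± 9.08 RPKM in GFP positive and 14692 ± 10660 in GFP negative pools (log2 difference -8.49 ± 1.15, adjusted p = 5.06e-06). Globin genes made up 0.00738 ± 0.00233% of all RPKM in GFP positive pools and 4.65 ± 3.32% in GFP negative pools, where the 6 pools ranged from 0.00537 to 9.59%. Of the 8 tested red blood cell genes 7 were lower (camera adjusted p = 2.21e-08; adjusted p = 0.0564 with an estimated correlation), as were 8 of 8 microglia and macrophage genes (2.21e-08; adjusted p = 0.0916 with an estimated correlation). The complement gene C1qb averaged 59.7 ± 38.4 RPKM in GFP negative pools and was listed at 0 in every GFP positive pool. Of 8 mesenchyme and pericyte genes 7 were lower, among them the collagen gene Col3a1 at 0.612 ± 0.883 against 72.9 ± 26.1 RPKM (-5.59 ± 0.29; adjusted p = 4.08e-13), with list p = 1.11e-11, and 0.000875 with an estimated correlation. Of 4 endothelial genes 3 were lower (0.0234; adjusted p = 0.237 with an estimated correlation). All 4 of these counts were the same adjusted over the list alone. The 10 named genes with the largest decreases were the adult globin gene Hbb-bt, Col3a1, Sncg (-5.49), Apod, Arhgdib, Bgn (-5.02), Isl1, the scavenger receptor gene Stab1, the metallothionein gene Mt1 (-4.69) and Dlx1. Globin copies are near-identical in sequence, so the split between Hbb-bt and its paralogs is uncertain.

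Of the 15871 genes tested at E10.5, 715 were higher and 1371 lower in GFP positive pools (limma, Benjamini-Hochberg adjusted p under 0.05), 395 and 885 of them by at least 2-fold. In 1204 genes (7.59%) the 6 values of one class did not overlap those of the other, against 0.216% by chance. Among the other lists, 3 of 4 roof plate and choroid plexus genes were higher, Folr1 and Bmp7 (1.75) included (0.000308; 0.0127 with an estimated correlation), and 1 more was lower when adjusted over the list alone. Of 12 cell cycle genes, Mki67 alone was higher (1.005, adjusted p = 0.0263, lost in 3 of 12 fits without 1 pool), also adjusted over the list alone, and the list call (0.00754) was lost with adjusted p = 0.381 with an estimated correlation. Of 9 Wnt signalling genes 3 were higher, Axin2 (0.87) included, and 5 adjusted over the list alone (0.0243; adjusted p = 0.192 with an estimated correlation). The diencephalon and hypothalamus, neural progenitor, serotonergic, hindbrain, forebrain, early response, hedgehog and axon guidance lists were not called, with adjusted p from 0.0736 (hedgehog) to 0.585 (serotonergic and hindbrain). Of 12 neural progenitor genes 4 were higher and 3 lower, or 6 and 3 adjusted over the list alone, Hes1 (1.80) and Pax6 (-3.95) going opposite ways, and the list's median (0.36) and mean (-0.15) differ in sign. Of 9 hedgehog genes 3 were lower, Gli1 (-1.88) included, the same number adjusted over the list alone.

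At E13.5, the same comparison showed the genes that mark GFP positive cells once neurons have formed. Pitx3, a homeobox gene of midbrain dopamine neurons, averaged 79.98 ± 32.04 RPKM in GFP positive pools (SD, n = 6) and was listed at 0 in all 6 GFP negative pools (adjusted p = 1.68e-14). Th averaged 191 ± 71.6 against 10.1 ± 8.17 RPKM (log2 difference 4.57 ± 0.62, adjusted p = 1.3e-05), Nr4a2 340.5 ± 48.5 against 19.3 ± 7.10 (4.14 ± 0.27; adjusted p = 5.82e-11) and the dopamine transporter gene Slc6a3 31.9 ± 23.3 against 0.198 ± 0.485 (4.46 ± 0.39; adjusted p = 1.12e-08). Of the 14 dopamine neuron genes 10 were higher, and 11 adjusted over the list alone (camera adjusted p = 9.69e-20, and 1.96e-06 with an estimated correlation). Barhl1 averaged 194 ± 15.7 against 18.6 ± 10.4 RPKM (3.56 ± 0.37; adjusted p = 1.66e-07). Of the 5 subthalamic lineage genes 4 were higher, and 5 adjusted over the list alone (1.15e-10; 0.000473 with an estimated correlation). Of 12 floor plate genes 10 were higher, Msx1 and Lmx1b included (4.31 and 3.65), and 11 adjusted over the list alone (8.99e-29; 2.94e-09 with an estimated correlation). Wnt5a, a Wnt ligand, averaged 167.5 ± 59.5 against 7.70 ± 3.07 RPKM (4.28 ± 0.28; adjusted p = 5.82e-11).

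Genes of other neuron classes were lower in E13.5 GFP positive pools. Gad2, which encodes a GABA-synthesizing enzyme, averaged 5.56 ± 3.29 RPKM in GFP positive and 91.02 ± 20.6 in GFP negative pools (log2 difference -3.96 ± 0.31, adjusted p = 1.15e-09), and 9 of 10 GABAergic genes were lower, Gata3 (-4.78) included, also adjusted over the list alone (camera adjusted p = 7.11e-24; 1.96e-06 with an estimated correlation). Fev, a serotonergic transcription factor gene, averaged 33.4 ± 21.1 RPKM in GFP negative pools and was listed at 0 in all 6 GFP positive pools, and both tested serotonergic genes were lower (1.47e-06; 0.0018 with an estimated correlation). Tcf7l2, a Wnt pathway transcription factor gene, averaged 34.6 ± 14.5 against 722 ± 293 RPKM (-4.35 ± 0.26; adjusted p = 7.72e-12). Of 7 red nucleus and basal plate genes 6 were lower, Lhx1 (-3.87) included (5.29e-10; 6.2e-05 with an estimated correlation), and 1 was higher adjusted over the list alone. All 4 tested forebrain genes were lower, Six3 (-3.04) and Emx2 (-3.19) included (4.52e-09; 0.000105 with an estimated correlation). Of 8 diencephalon and hypothalamus genes Wnt8b (2.31) and Dbx1 (2.20) were higher and 4 were lower, Nkx2-1 (-3.66) and Sim1 (-3.55) included. That list's call (0.00975) was lost with adjusted p = 0.159 with an estimated correlation.

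In all, 542 genes were higher and 593 lower in E13.5 GFP positive pools (limma, 15871 genes tested), 347 and 321 by at least 2-fold, and 635 genes (4.001%) did not overlap between classes, against 0.216% by chance. The named genes with the largest increases also included Rspo2 (4.52), Ccdc3 (4.16), Lmx1a and the unannotated transcript C130021I20Rik. Those with the largest decreases were the neuropeptide gene Cartpt (-6.03), Dlx1, Six3os1, the somatostatin gene Sst (-4.89), Fev, Gchfr, Gata3, Gad1, Tcf7l2 and Gata2. Six3os1 is antisense to Six3, and the sources used here do not say that reads were counted by strand, so its value is uncertain. Of 12 neural progenitor genes 9 were higher, Nes (1.74) and Sox9 (1.71) included, while Pax6 (-3.18) and Sox1 (-2.15) were lower, also adjusted over the list alone (1.36e-08; 0.00377 with an estimated correlation). Of 15 axon guidance genes 5 were higher, Slit2 (2.65) and Ntn1 (2.21) included, and 1 was lower, or 5 and 2 adjusted over the list alone (0.00138; 0.019 with an estimated correlation). Of 4 roof plate genes 2 were higher, and 3 adjusted over the list alone (0.000242; 0.00881 with an estimated correlation). No cell cycle gene of 12 passed the test over all genes, 6 were higher adjusted over the list alone, and the list call (3.19e-05) was lost with adjusted p = 0.161 with an estimated correlation. Pan-neuronal genes were not called as a list (0.0588), with 1 of 12 higher and 2 lower, or 1 and 4 adjusted over the list alone, and Tubb3 did not pass the test (-0.09 ± 0.13; adjusted p = 0.77). Red blood cell genes (1 of 8 lower, 2 adjusted over the list alone, 0.00195), motor neuron genes (1 of 3 lower, 0.0459) and Wnt signalling genes (3 of 9 higher and 1 lower, 3 and 2 adjusted over the list alone, 0.00448) lost their calls with adjusted p = 0.254, 0.097 and 0.097 with an estimated correlation. The proneural, hindbrain, endothelial, microglia, mesenchyme, early response and hedgehog lists were not called (adjusted p from 0.0877 for microglia to 0.821 for proneural and endothelial). The endothelial list tested upward while its median (-0.46) and mean (-0.12) lay below 0.

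**Figure D2:**
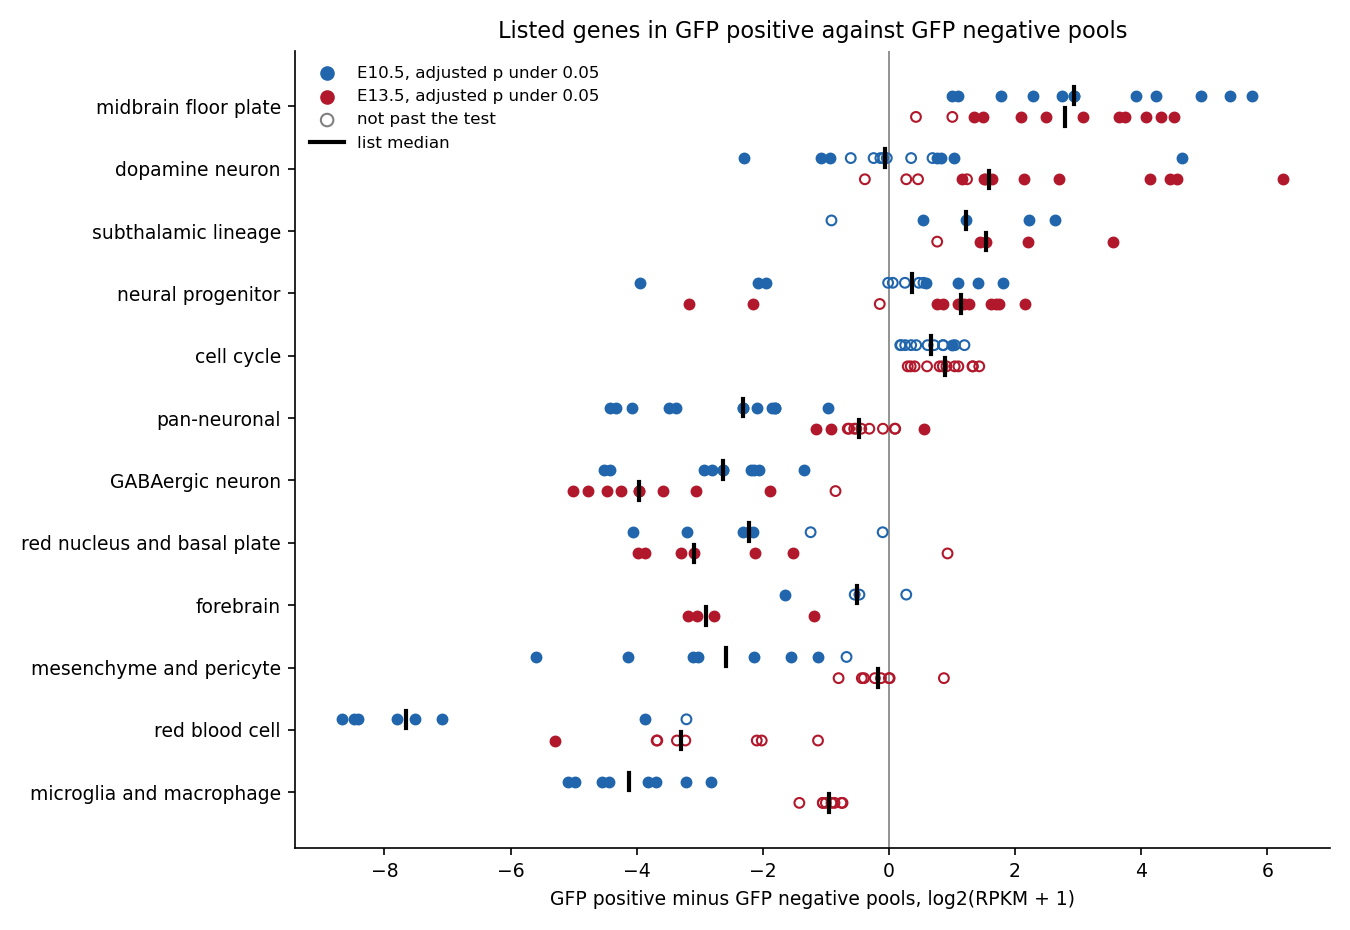
Log2 difference between GFP positive and GFP negative pools (x axis, log2(RPKM + 1)) of each tested gene of 12 gene lists fixed in advance (y axis), at E10.5 (blue) and E13.5 (red), with filled points for an adjusted p under 0.05 and black lines for list medians. Floor plate genes lay above 0 at both stages, and 10 of 14 dopamine neuron genes were higher at E13.5 against 4 at E10.5.

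Genes called at both stages overlapped beyond what independent lists would share. Of the 715 and 542 genes higher in GFP positive pools at E10.5 and E13.5, 170 were shared, among them Lmx1a, Rspo2, Foxa1 (2.28 and 3.08) and Barhl1, against 24.4 for independent lists (Fisher's exact test p = 1.77e-99, across genes, which are not independent replicates). Of the 1371 and 593 lower genes 184 were shared, Isl1 (-4.77 and -3.79) and Dlx1 (-4.52 and -5.00) included, against 51.2 (p = 1.4e-57). Only 28 genes were called in opposite directions, among them Fabp7 (-1.96 and 1.26), Ret (-1.07 and 2.69) and Slc18a2 (-0.93 and 1.53), 1 call of each being lost in 5 to 8 of 12 fits without 1 pool. The pools of the stages are separate libraries, although all 24 share 1 estimate of the spread.

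In GFP positive pools, E13.5 was compared with E10.5 to follow Lmx1a-expressing cells through neurogenesis. Mapt, which encodes the axonal protein tau, rose from 3.31 ± 1.503 to 675 ± 98.7 RPKM (SD, n = 6 each; log2 difference 7.37 ± 0.20, adjusted p = 1.62e-19), and the neuronal gene Stmn2 from 53.5 ± 29.6 to 919 ± 59.4 (4.30 ± 0.26; adjusted p = 3.69e-13). All 12 pan-neuronal genes rose, also adjusted over the list alone (camera adjusted p = 5.5e-13, and 0.0195 with an estimated correlation). Nr4a2 rose by 4.42 ± 0.27 (adjusted p = 5.2e-13), Th by 2.97 ± 0.62 (0.000258) and Pitx3 from 0.446 ± 0.592 to 79.98 RPKM (5.80 ± 0.27; 2.17e-15). Of the 14 dopamine neuron genes 11 rose, or 12 adjusted over the list alone, and Aldh1a1 fell by 3.37 (3.87e-06; 0.0125 with an estimated correlation). Of the 5 subthalamic lineage genes 4 rose, also adjusted over the list alone, Barhl1 by 1.71 ± 0.37 and Slc17a6 from 3.89 ± 3.04 to 81.4 ± 18.95 RPKM (4.27 ± 0.34; adjusted p = 5.79e-11). The subthalamic list call (0.00318) was lost with adjusted p = 0.11 with an estimated correlation. Of 15 axon guidance genes 8 rose, Robo2 (4.66) and Dcc (2.84) included, and 2 fell (0.00655; adjusted p = 0.0717 with an estimated correlation).

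Genes of dividing cells fell over the same interval. The topoisomerase gene Top2a went from 334 ± 41.1 to 14.4 ± 6.08 RPKM (log2 difference -4.53 ± 0.47, adjusted p = 8.43e-09) and the proliferation marker Mki67 from 51.6 ± 4.75 to 4.42 ± 1.77 (-3.33 ± 0.30; adjusted p = 7.87e-10). All 12 cell cycle genes fell, also adjusted over the list alone, while the list call (1.24e-07) was lost with adjusted p = 0.131 with an estimated correlation. Of 12 floor plate genes 9 fell, also adjusted over the list alone, with log2 differences of -2.99 for Shh and -3.27 for Wnt1 (0.0103; 0.0375 with an estimated correlation). Vtn, the vitronectin gene, had one of the largest decreases, from 342 ± 56.5 to 3.68 ± 4.03 RPKM (-6.52 ± 0.36; adjusted p = 4.55e-14). Genes with the largest increases included Mapt, Ndst3, Celf5, the calretinin gene Calb2 (6.02), St8sia3, Sez6l, Pitx3, Xist and E130114P18Rik. Those with the largest decreases were Vtn, the carbonic anhydrase gene Car4 (-5.93), Cmtm8, Fndc3c1, Dkk2 (-5.18), Calca, Gm15452, the glypican gene Gpc3, Lrtm1 and the cyclin gene Ccnb1 (-4.57). Gm15452 is a predicted gene and its value is uncertain where reads are shared with similar loci.

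In GFP positive pools 3506 genes were higher and 4697 lower at E13.5 (limma, 15871 genes tested), 2370 and 2850 by at least 2-fold. Values of 4745 genes (29.9%) did not overlap between stages, against 0.216% by chance. Xist, the RNA that coats the inactive X chromosome, rose from 0.457 ± 0.323 to 79.3 ± 13.46 RPKM (5.79 ± 0.19; adjusted p = 2.88e-18), and the Y-linked genes Ddx3y (-1.85), Eif2s3y (-2.58) and Uty (-1.34) fell. Of the called genes with a known chromosome 4.57% lay on X or Y, against 4.71% of those tested. Mitochondrial genes made up a median of 8.74% (8.09 to 9.26) of RPKM in GFP positive pools at E10.5 and 13.6% (11.2 to 15.1) at E13.5. The other 17 lists were not called (adjusted p from 0.056 for diencephalon and hypothalamus to 0.804). Neural progenitor genes, for example, had 1 of 12 higher and 6 lower (0.0801), also adjusted over the list alone.

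In GFP negative pools, E13.5 was compared with E10.5 in the same way. Tmem130, a transmembrane protein gene, rose from 7.85 ± 3.69 to 279.5 ± 44.8 RPKM (SD, n = 6 each; log2 difference 5.07 ± 0.27, adjusted p = 1.4e-13). Fev rose from 0.728 ± 0.952 to 33.4 RPKM (4.24 ± 0.34; adjusted p = 1.47e-10) and Gad2 from 6.71 ± 3.35 to 91.02 (3.66 ± 0.31; adjusted p = 3.64e-10). The growth factor gene Igf2 fell from 352 ± 311 to 0.705 ± 0.771 RPKM (-7.23 ± 0.78; adjusted p = 2.19e-08), Col3a1 from 72.9 to 0.0929 ± 0.0595 (-5.997 ± 0.29; adjusted p = 3.65e-14) and the Notch target Hes1 from 146.5 ± 14.4 to 14.5 ± 6.03 (-3.38 ± 0.26; adjusted p = 5.95e-11). The named genes with the largest increases were Xist (0.260 ± 0.182 to 81.7 ± 15.4 RPKM), Tmem130, Nkain2, the calcium sensor gene Vsnl1 (4.40), 2900055J20Rik, Kndc1, AW551984, Fev, the calmodulin-binding protein gene Pcp4 (4.21) and Sez6. Those with the largest decreases were Igf2, Vtn (-6.60), Col3a1, Fndc3c1, the proteoglycan gene Lum (-5.97), the galectin gene Lgals1, Eif4ebp1, Pcolce, the mitotic survivin gene Birc5 (-5.02) and Cmtm8.

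In GFP negative pools 3126 genes were higher and 4262 lower at E13.5, 1993 and 2496 by at least 2-fold, and 4061 genes (25.6%) did not overlap between stages, against 0.216% by chance. Pan-neuronal genes rose in 10 of 12 cases and fell in 1 (camera adjusted p = 0.000104; adjusted p = 0.127 with an estimated correlation). GABAergic genes rose in 6 of 10 and fell in 1, or 7 and 1 adjusted over the list alone (0.00543; adjusted p = 0.0971 with an estimated correlation). All 12 cell cycle genes (2.18e-09), all 8 mesenchyme genes (5.2e-06) and all 8 microglia genes (0.0122) fell. These list calls were lost with adjusted p = 0.0831, 0.0569 and 0.379 with an estimated correlation. Of 12 neural progenitor genes 8 fell (1.85e-05; adjusted p = 0.0569 with an estimated correlation), of 8 red blood cell genes 6 (0.0209; 0.379 with an estimated correlation) and of 9 hedgehog genes 7, Ptch1 (-0.88) included (0.0128; 0.0806 with an estimated correlation). Of 15 axon guidance genes 10 rose and 1 fell (0.00248; adjusted p = 0.0569 with an estimated correlation), and of 5 subthalamic genes 4 rose (0.00845; 0.127 with an estimated correlation). Of 9 early response and heat shock genes 6 fell, or 7 adjusted over the list alone (0.0055; 0.127 with an estimated correlation), and of 13 proneural genes 9 (0.00751; 0.238 with an estimated correlation). Both serotonergic genes rose (0.00956; 0.0971 with an estimated correlation), 6 of 9 Wnt signalling genes fell (0.0189; 0.166, likewise) and 2 of 3 motor neuron genes fell (0.0483; 0.127, likewise). Except where given, these counts were the same adjusted over the list alone. No list was called with an estimated correlation in these pools. The dopamine neuron list was not called (camera adjusted p = 0.062), although 6 of 14 genes rose and 0 fell, also adjusted over the list alone. The floor plate list was not called either (0.0961), with 6 of 12 genes lower and 0 higher, or 6 and 2 adjusted over the list alone. Among other lists not called, diencephalon and hypothalamus genes tested upward with a median of -0.10 and a mean of -0.09, and red nucleus genes downward with a median of 0.11 and a mean of -0.43.

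In GFP negative pools too Xist rose and Ddx3y (-2.31) and Eif2s3y (-2.56) fell. Kdm5d fell in GFP negative pools (-1.68) and did not pass the test in GFP positive pools (-0.54, adjusted p = 0.0639). The mitochondrial share had medians of 8.51% (7.14 to 9.06) and 11.1% (9.74 to 12.7). Of the genes higher at E13.5 in the GFP positive and GFP negative pools, 2416 were shared, Mapt (7.37 and 3.87) included, against 691 for independent lists. Of the lower genes 3278 were shared, Top2a (-4.53 and -3.97) included, against 1261. Only 40 genes went in opposite directions, among them Tcf7l2 (-1.75 and 2.54), Nkx2-1 (-2.11 and 1.34) and Emx2 (-1.48 and 1.25).

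The difference between GFP positive and GFP negative pools itself differed between stages for 623 genes that were relatively higher and 302 that were relatively lower in GFP positive pools at E13.5 (limma, 15871 genes). Nr4a2 shifted by 3.32 ± 0.39 (SE; adjusted p = 2.87e-06), from a log2 difference of 0.82 at E10.5 to 4.14 at E13.5, and Th by 3.88 ± 0.88 (0.0068). Of the 14 dopamine neuron genes 8 shifted upward and 2 downward, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.58e-10, and 0.000522 with an estimated correlation). Of 5 subthalamic lineage genes 2 shifted upward, Slc17a6 (1.68 ± 0.48, adjusted p = 0.0341, lost in 11 of 24 fits without 1 pool) included, and 3 adjusted over the list alone, while Barhl1 (1.34 ± 0.52, adjusted p = 0.146) did not pass the test over all genes. That list's call (0.0262) was lost with adjusted p = 0.188 with an estimated correlation. Pan-neuronal genes shifted upward in 11 of 12 cases, 12 adjusted over the list alone, Stmn2 by 3.07 and Tubb3 by 1.99 (1.39e-25; 0.000615 with an estimated correlation). Tcf7l2 (-4.28 ± 0.36, adjusted p = 2.33e-08) and Wnt1 (-3.32 ± 0.55, adjusted p = 0.000263) shifted downward. The floor plate list had 3 of 12 genes downward, with 2 upward and 5 downward adjusted over the list alone, and lost its call (0.0425) with adjusted p = 0.0794 with an estimated correlation.

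Other lists also differed between stages in this way. Neural progenitor genes shifted upward in 5 of 12 cases, Fabp7 by 3.22, with 6 upward and 1 downward adjusted over the list alone (7.91e-05; 0.0471 with an estimated correlation). Serotonergic genes (2 of 2 downward, 7.91e-05; 0.00904 with an estimated correlation) and forebrain genes (3 of 4 downward, 4 adjusted over the list alone, 6.25e-05; 0.00424 with an estimated correlation) held their calls, as did motor neuron genes (2 of 3 upward, 0.000156; 0.00424) and mesenchyme genes (5 of 8 upward, 7 adjusted over the list alone, 1.58e-10; 0.0029). The motor neuron and mesenchyme shifts came with falls in GFP negative pools, of 2 of 3 and 8 of 8 genes from E10.5 to E13.5. In GFP positive pools 0 motor neuron genes rose or fell, and 0 mesenchyme genes rose and 3 fell. For microglia genes 0 of 8 passed the test over all genes, and all 8 shifted upward adjusted over the list alone (6.25e-05; adjusted p = 0.192 with an estimated correlation). Between the stages all 8 microglia genes fell in GFP negative pools, and 0 of 8 rose or fell in GFP positive pools. Proneural (3 of 13 upward, 0.000365), red blood cell (2 of 8 upward, 4 adjusted over the list alone, 0.00136), diencephalon (4 of 8 downward, 0.000198) and GABAergic genes (2 of 10 downward, 4 adjusted over the list alone, 0.00815) lost their calls with adjusted p = 0.18, 0.233, 0.0535 and 0.111 with an estimated correlation. The same held for endothelial (0 of 4, 2 upward adjusted over the list alone, 0.02) and early response genes (1 of 9 upward, 2 adjusted over the list alone, 0.0442), with adjusted p = 0.209 and 0.253 with an estimated correlation. The red nucleus list, not called (0.429), tested downward with a median of 0.12 and a mean of -0.23. The GABAergic list also turned direction with a pseudocount of 0.1, where it was not called (adjusted p = 0.708). The named genes with the largest upward shifts were Hbb-bh1, Pitx3, Hba-x, Col3a1, Igf2 (4.78), Slc6a3 (4.60), Bgn, Arhgdib, Cd248 and Stab1. Means of Hbb-bh1, Hba-x, Col3a1, Igf2, Bgn, Arhgdib, Cd248 and Stab1 fell in GFP negative pools from E10.5 to E13.5. Col3a1 went from 72.9 to 0.0929 RPKM there and from 0.612 to 0 RPKM in GFP positive pools. Those with the largest downward shifts were Tcf7l2, Fev, Gchfr, Dkk2 (-3.80), Tac1, Nav3, Nkx2-1 (-3.45), Cartpt, Aldh1a1 and Calca. The calls of Hba-x and Cartpt were lost in 15 and 7 of 24 fits without 1 pool.

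In single cells, shares of cells with a gene at an RPKM of at least 10 followed similar lines. Intervals given with shares are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only, and no p-value is given because each stage is 1 sample. Lmx1a was found in 71.5% (63.2 to 78.9) of cells at E10.5, 42.2% (31.9 to 53.1) at E11.5, 50.6% (42.98 to 58.1) at E12.5 and 50.3% (41.9 to 58.7) at E13.5. Foxa2 was found in 62.04% (53.4 to 70.2) of E10.5 and 25.5% (18.6 to 33.4) of E13.5 cells. Nr4a2 was found in 6.57% (3.05 to 12.1) of cells at E10.5 and 42.8% (34.6 to 51.2) at E13.5, and Pitx3 in 0% of cells at E10.5, which leaves an upper limit of 2.66%, and 17.2% (11.48 to 24.4) at E13.5. Barhl1 was found in 27.01% (19.8 to 35.3) and 34.5% (26.8 to 42.8) of cells at those stages, and Slc17a6 in 3.65% (1.195 to 8.31) and 49.7% (41.3 to 58.1). Mki67 went from 50.4% (41.7 to 59.01) to 2.76% (0.757 to 6.91) and Stmn2 from 8.76% (4.61 to 14.8) to 82.1% (74.8 to 87.9). The median number of genes at an RPKM of at least 1 was 5747, 3567, 4266 and 4287 at the successive stages, with median implied depths of 1.29, 0.746, 1.40 and 1.77 M reads, and without read counts the cells could not be brought to 1 depth.

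Cells that met a marker gate of dopamine neurons or a gate on Barhl1, a gene of the subthalamic list, were present from E10.5 on. The dopamine gate required Th and Nr4a2, and the Barhl1 gate Barhl1 alone, each at an RPKM of at least 10. The Barhl1 gate was chosen after the data were seen, and Barhl1 alone does not tell subthalamic cells from other Barhl1-expressing cells. Cells in the dopamine gate alone made up 1.46% (0.177 to 5.17) of cells at E10.5, 7.78% (3.18 to 15.4) at E11.5, 5.62% (2.73 to 10.1) at E12.5 and 13.8% (8.63 to 20.5) at E13.5. Cells in the Barhl1 gate alone made up 27.01% (19.8 to 35.3), 26.7% (17.9 to 37.03), 28.1% (21.6 to 35.3) and 34.5% (26.8 to 42.8) of cells. Only 2 cells met the dopamine gate at E10.5. Tubb3, Dcx, Pitx3 and En1 were each found in 0 of these 2, and Lmx1a and Foxa2 in 2 of 2. Meeting the gate at E10.5 therefore does not show that dopamine neurons were present. At E12.5 the cells whose titles start with C held 6.35% dopamine-gated and 26.98% Barhl1-gated cells, and those starting with F 5.22% and 28.7%. The other stages have no such division. Both gates were met by 4 cells in all, against 12.9 if the gates were independent over all cells. By stage the counts were 0 at E10.5, 2 at E11.5, 2 at E12.5 and 0 at E13.5, where independence within the stage would give 0.540, 2.60, 3.51 and 6.90. At an RPKM of at least 1 both gates were met by 20 cells in all against 25.9, by 9 against 8.49 at E12.5 and by 6 against 12.6 at E13.5. The lower of the gate genes lay between 5 and 20 RPKM in 4 cells for the dopamine gate, and Barhl1 did so in 5 cells.

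**Figure D3:**
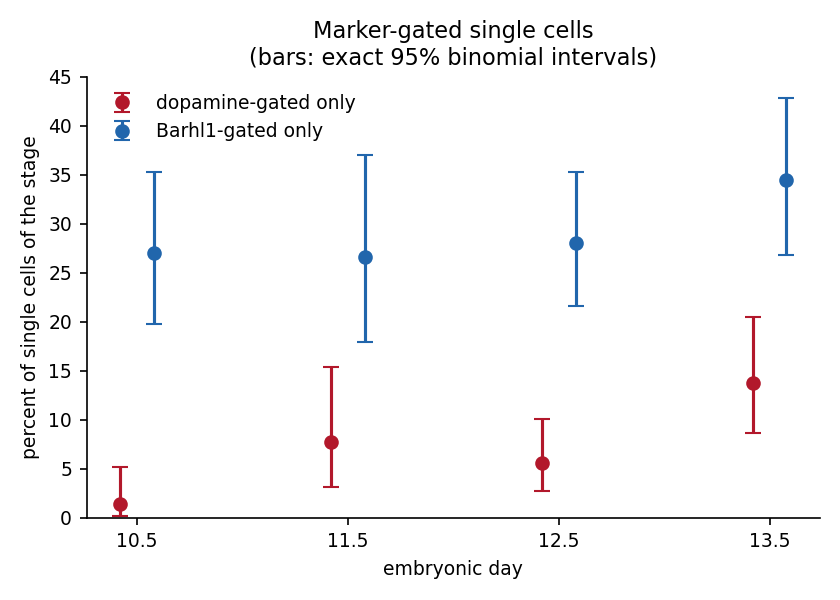
Percent of single cells of each stage (y axis) that met the dopamine gate alone (red) or the Barhl1 gate alone (blue), by embryonic day (x axis), with exact 95% binomial intervals for counting error as bars. Barhl1-gated cells lay at 34.5% and dopamine-gated cells at 13.8% at E13.5.

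The gated classes were compared over the listed genes other than the gate genes, pooled over stages. The dopamine gate alone held 39 cells, and the Barhl1 gate alone 37, 24, 50 and 50 cells at the successive stages. Lmx1a was found at like shares, 71.8% (55.1 to 84.999) of dopamine-gated and 71.4% (63.8 to 78.3) of Barhl1-gated cells, against 43.9% (38.6 to 49.3) of cells in neither gate. Foxa2 was found in 76.9% (60.7 to 88.9) of dopamine-gated and 20.5% (14.5 to 27.6) of Barhl1-gated cells. The latter share was 35.7% at an RPKM of at least 1 and 30.3% among cells with at least 4000 genes, against 75.6% and 72% of dopamine-gated cells. The dopa decarboxylase gene Ddc (84.6% against 12.4%), the monoamine transporter gene Slc18a2 (69.2% against 4.35%), Pitx3 (66.7% against 1.24%) and En1 (61.5% against 2.48%) were more frequent in dopamine-gated cells. Barhl2 (0% against 46.6%), Dbx1 (0% against 45.96%), Nkx2-1 (0% against 34.2%), Wnt8b (0% against 37.3%) and the ephrin receptor gene Epha3 (2.56% against 56.5%) were more frequent in Barhl1-gated cells. A share of 0 of 39 cells leaves an upper limit of 9.03%. Foxp2 was found in 94.9% (82.7 to 99.4) of dopamine-gated and 74.5% (67.1 to 81.1) of Barhl1-gated cells, although it is on the subthalamic list, and Slc17a6 in 46.2% (30.1 to 62.8) and 42.9% (35.1 to 50.9). Of 205 genes compared, 42 had intervals apart, 22 with the higher share in dopamine-gated and 20 in Barhl1-gated cells.

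By stage, Foxa2 was found in 20 of 37 Barhl1-gated cells (36.9 to 70.5%) at E10.5, 5 of 24 (7.13 to 42.2%) at E11.5, 6 of 50 (4.53 to 24.3%) at E12.5 and 2 of 50 (0.488 to 13.7%) at E13.5. Over the same stages Lmx1a was found in 33 of 37 (74.6 to 96.97%), 15 of 24 (40.6 to 81.2%), 32 of 50 (49.2 to 77.1%) and 35 of 50 (55.4 to 82.1%) of them. In dopamine-gated cells Foxa2 was found in 10 of 10 cells at E12.5 and 12 of 20 (36.1 to 80.9%) at E13.5, and Lmx1a in 6 of 10 (26.2 to 87.8%) and 15 of 20 (50.9 to 91.3%). The like pooled shares of Slc17a6 hide different courses. Barhl1-gated cells had it in 2 of 37, 9 of 24, 24 of 50 and 34 of 50 (53.3 to 80.5%) cells at the successive stages. Dopamine-gated cells had it in 0 of 2, 6 of 7, 5 of 10 and 7 of 20 (15.4 to 59.2%). The intervals at E13.5 overlapped. Wnt8b was found in 32 of 37, 6 of 24, 15 of 50 and 7 of 50 Barhl1-gated cells at the successive stages. It was found in 0 dopamine-gated cells, with intervals that overlapped those of Barhl1-gated cells at every stage. Dbx1 intervals were apart at E12.5 (0 to 30.8% against 31.8 to 60.7%) and at E13.5 (0 to 16.8% against 22.9 to 50.8%). Barhl2, Nkx2-1 and Epha3 were not split by stage. The stages are unevenly represented, with 2 dopamine-gated cells at E10.5, so shares pooled over stages mix different stage mixtures. Progenitor genes in Barhl1-gated cells, such as Sox9 (57.8% against 7.69%) and Hes5 (38.5% against 2.56%), are read under the same limit. Median depths were 1.72 M implied reads in dopamine-gated and 1.45 M in Barhl1-gated cells, with medians of 4453 and 4356 genes.

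**Figure D4:**
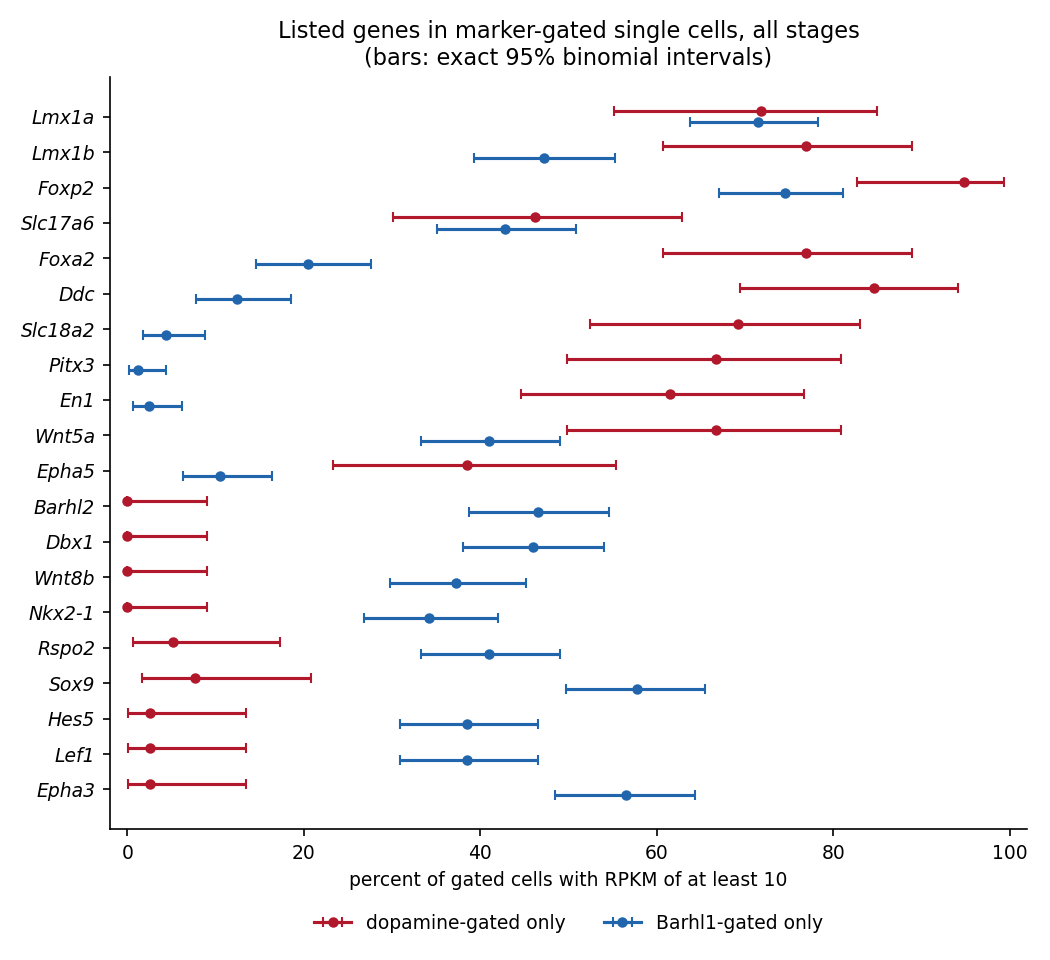
Percent of dopamine-gated (red) and Barhl1-gated (blue) single cells with each of 20 listed genes at an RPKM of at least 10 (x axis), pooled over stages, with exact 95% binomial intervals for counting error as bars. Lmx1a lay at 71.8% and 71.4%, while Foxa2 lay at 76.9% and 20.5%.

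Clustering of the 550 cells gave 9 clusters, 8 of which were named from the fixed marker lists. The dopamine neuron-like cluster (37 cells) held 0% of cells at E10.5 (upper limit 2.66%), 1.11% (0.0281 to 6.04) at E11.5, 7.30% (3.95 to 12.2) at E12.5 and 15.9% (10.3 to 22.8) at E13.5. The subthalamic lineage-like cluster (43 cells) held 0%, 17.8% (10.52 to 27.3), 9.55% (5.66 to 14.9) and 6.90% (3.36 to 12.3). No cluster of that name was found in 3 of 7 alternative clusterings, and no dopamine neuron-like cluster in 1 of them. Clusters named cell cycle-like or neural progenitor-like together held 91.97% (86.1 to 95.9), 27 of 90 cells (20.8 to 40.6%), 17.4% (12.2 to 23.8) and 15.2% (9.76 to 22.1) of cells. These are different clusters at the end stages: cell cycle-like cluster 0 held 94 and progenitor-like cluster 3 held 32 of the E10.5 cells, while at E13.5 progenitor-like cluster 8 held 10, cluster 3 held 9 and cluster 0 held 3. Pan-neuronal-like clusters 1 and 2 held 90 and 86 cells and the proneural-like cluster 4 held 59. The unnamed cluster 7 (29 cells, median 2072 genes) held 0%, 16.7%, 7.30% and 0.690% of cells at the successive stages, and it stayed unnamed under a score limit set after the data were seen. Of the 39 dopamine-gated cells 24 lay in the dopamine neuron-like cluster and 7 and 3 in the pan-neuronal-like clusters. The cell cycle-like and unnamed clusters held 2 each and the subthalamic lineage-like cluster 1. The dopamine neuron-like cluster was named from a list that holds both gate genes, so this agreement was partly built in. Barhl1-gated cells, from a gate on 1 gene, were spread, with 39 in the cell cycle-like cluster, 34 in the proneural-like cluster, 28 and 19 in the pan-neuronal-like clusters and 21 in the subthalamic lineage-like cluster.

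The direction of stage differences in the means over single cells was set against that in GFP positive pools. Of 3505 genes higher at E13.5 in the pools and present in both tables, 3124 (89.1%) were also higher in the mean over E13.5 than over E10.5 cells, and of 4695 lower genes 4266 (90.9%) were lower. The labels do not give the GFP status of the single cells. Listed genes called in the pools mostly went the same way, Map2 (2.28 in cells and 3.11 in pools) included. The 6 that went the opposite way were Lum (0.35 in cells and -2.93 in pools), Fos (0.49 and -0.78), Emx2 (0.66 and -1.48), Lhx2 (2.96 and -0.92), Hes5 (0.96 and -0.91) and Lhx5 (0.60 and -1.27). The pool call of Lhx2 was lost in 10 of 12 fits without 1 pool.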

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

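The test of Y-linked genes against stage was chosen only after the results were seen, and the alternative without globin genes was added after the data were seen.

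In 5 sets of 6 pools, each set being 1 gene or library measure in 1 group, 1 pool lay far from the other 5. EGFP was 80.3 RPKM in E13.5 GFP positive replicate 1, against 51.1 to 61.6 in the others. Rspo2 was 0.688 in E10.5 GFP negative replicate 2 (others 0 to 0.248), and Wnt1 was 0.588 in E10.5 GFP negative replicate 6, with the others at 0. Slc6a3 was 1.19 in E13.5 GFP negative replicate 4, with the others at 0, and Vtn was 11.7 in E13.5 GFP positive replicate 2 (others 0.321 to 2.86). Among 85 such sets tested, chance alone would give about 4.25, or 1 in 20, if values were normally distributed. That figure does not hold for sets such as Wnt1 and Slc6a3. With the other 5 pools at 0, any value above 0 would have been flagged there.

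The GFP difference itself differed between stages in 623 genes upward and 302 downward, and in 16 of 23 lists, or 7 with an estimated correlation. Upward shifts (log2) were 6.395 for Hbb-bh1, 5.89 for Pitx3, 5.71 for Hba-x, 5.47 for Col3a1, 4.78 for Igf2, 4.60 for Slc6a3, 4.49 for Bgn, 4.28 for Arhgdib, 4.13 for Cd248 and 4.01 for Stab1. Among other reported genes they were 3.88 for Th, 3.50 for Mapt, 3.48 for Wnt5a, 3.32 for Nr4a2, 3.07 for Stmn2, 1.99 for Tubb3 and 1.68 for Slc17a6. Means of Hbb-bh1, Hba-x, Col3a1, Igf2, Bgn, Arhgdib, Cd248 and Stab1 fell in GFP negative pools between the stages. Their upward shifts therefore do not show a gain in GFP positive pools. Downward shifts were -4.28 for Tcf7l2, -4.24 for Fev, -4.00 for Gchfr, -3.80 for Dkk2, -3.71 for Tac1, -3.52 for Nav3, -3.45 for Nkx2-1, -3.41 for Cartpt, -3.40 for Aldh1a1 and -3.35 for Calca, with -3.32 for Wnt1 and -1.24 for Rspo2. Pitx3, Fev, Col3a1, Arhgdib, Stab1 and Aldh1a1 are listed at 0 in every pool of at least 1 group, so the size of their shifts depends on the pseudocount. The same limit holds for other genes near 0 in a group. Wnt1 and Slc6a3 were at 0 in all but 1 pool of a GFP negative group. Rspo2 averaged 0.184 RPKM in E10.5 GFP negative pools, and its shift ran from -2.22 to -0.646 across the alternative fits. Without 1 pool, the calls of Rspo2, Hba-x, Slc17a6 and Cartpt were lost in 18, 15, 11 and 7 of 24 fits. Under other settings Rspo2 lost its call in 6 of 10, Hba-x in 5 of 9, Slc17a6 and Cartpt each in 2 of 10, Hbb-bh1 in 1 of 9 and Calca in 1 of 10.

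Whether other groupings of the same pools call as many genes was tested with 100 splits per comparison, the real one included. Only 1 of 100 splits, the real one, called as many genes in each comparison. The real and the highest other counts were 2086 and 598 for GFP at E10.5, 1135 and 186 for GFP at E13.5, 8203 and 4374 for stage in GFP positive pools, 7388 and 3777 for stage in GFP negative pools, and 925 and 8 for the difference between stages. In the GFP and the stage comparisons the real split thus called more genes than any other split drawn. Since the labels name no embryo or litter, the splits cannot tell GFP class or stage from anything else that the pools of a group share. For the difference between stages, GFP labels were shuffled within each stage, which also moves the GFP difference into the spread. Its splits therefore do not show how many genes would be called without a difference between stages.

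Xist was higher and Y-linked genes lower at E13.5 than at E10.5 in both GFP classes. A rise of Xist with stage in cells of either sex would not in itself lower Y-linked genes. At least 3 of 4 fell in each GFP class: Ddx3y and Eif2s3y in both, Uty in GFP positive and Kdm5d in GFP negative pools. That test was chosen after the results were seen, and a fall of Y-linked genes does not by itself exclude such a rise. Among single cells with a Y-linked gene, 1.63% (2 cells) also had Xist, and cells with a Y-linked gene went from 45.99% at E10.5 to 0% at E13.5. At E10.5 Xist was found in 1.59% of cells with a Y-linked gene and 31.1% of other cells, and at E12.5 in 0% and 79.6%. The E12.5 shares, with 16 cells that had a Y-linked gene, argue against a rise of Xist in cells of either sex by that stage. At E11.5 these shares were 2.27% and 2.17%, so that stage does not tell the explanations apart. Embryos of different sex at the stages are therefore a candidate explanation, which leaves sex and stage mixed in both stage comparisons. In single cells Xist was found in 17.5%, 2.22%, 72.5% and 93.8% of cells at the successive stages. A Y-linked gene was found in 45.99%, 48.9%, 8.99% and 0%. The same limit therefore holds for shares, gates and clusters of cells by stage, and for their comparison with pools. The labels give no sex, so no fit with sex as a term could be made.

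Blood, microglia and mesenchyme transcripts were higher in E10.5 GFP negative pools. With globin genes left out and pools rescaled, 579 genes were higher and 1589 lower in E10.5 GFP positive pools, against 715 and 1371 with them. Globin taking up reads would lower other transcripts in GFP negative pools, so it does not bear on why microglia and mesenchyme transcripts were higher there. All 3 lists were lower in GFP positive pools, with 7 of 8, 8 of 8 and 7 of 8 genes called, which restates the pattern and does not show where the transcripts came from. Cells of these types inside the GFP negative gate stay open. The microglia and red blood cell lists did not hold with an estimated correlation (adjusted p = 0.0916 and 0.0564). Globin made up 0.00537 to 9.59% of RPKM in single GFP negative pools.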

How the results depend on the processing

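Leaving out globin genes and the Barhl1 gate with all its alternatives were chosen only after the data were seen, and all other alternatives were planned. Without 1 pool, all counts of called genes stayed within 1.5 times the count with all pools. They ranged from 607 to 696 higher and 1217 to 1366 lower for GFP at E10.5, 457 to 553 and 483 to 614 for GFP at E13.5, 3342 to 3475 and 4492 to 4607 for stage in GFP positive pools, 2912 to 3086 and 3957 to 4194 in GFP negative pools, and 558 to 722 and 248 to 348 for the difference between stages. Under other settings 12 counts went outside that limit. The balance of directions also depended on the setting. For stage in GFP negative pools 42.3% of called genes were higher, and 49.5% with quantile normalization. For GFP at E10.5 the share was 34.3%. It was 40.7% with quantile normalization, 42.1% with only the groups compared, 43.6% with a pseudocount of 10 and 26.7% without globin genes.

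With a fold change of at least 2 also required, fewer genes passed by construction: 395 higher and 885 lower for GFP at E10.5, 347 and 321 for GFP at E13.5, 2850 lower for stage in GFP positive pools, and 1993 higher and 2496 lower in GFP negative pools. With a mean RPKM of at least 10, fewer genes were tested, which gave 448 higher for GFP at E10.5, 2291 higher for stage in GFP positive pools, 1989 higher and 2832 lower in GFP negative pools, and 200 lower for the difference between stages.

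With an estimated correlation, 8 lists were called for GFP at E10.5, 3 for stage in GFP positive pools, 0 in GFP negative pools and 7 for the difference between stages. Of 345 single list results 301 were counted as kept, 42 lost the call, 1 gained it and 1 turned. A turn was counted only for lists or genes called in the main fit. Kept results that were not called there may therefore have changed direction. The list that turned was the GABAergic list in the difference between stages with a pseudocount of 0.1 (adjusted p = 0.708; 0.111 with an estimated correlation; the cause was not tested). Of single genes, 14019 of 14508 results without 1 pool and 10211 of 10534 under other settings were kept, 354 and 203 lost the call, and 0 turned. Among them the E10.5 GFP call of Nr4a2 was lost in 8 of 12 fits without 1 pool and in 7 of 11 other settings, with adjusted p from 0.0126 to 0.134.

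At an RPKM of at least 1, 42.2% of E11.5 and 35.4% of E12.5 cells met the Barhl1 gate alone and 35.7% of Barhl1-gated cells had Foxa2, and at 30 or more 57.1% had Lmx1a. Among cells with at least 4000 genes these shares were 79.8% for Lmx1a and 30.3% for Foxa2. Progenitor-like clusters held 70.1% of E10.5 cells at resolution 2, 67.9% with 10 neighbours and 60.7% among cells with at least 4000 genes. The share of genes with the same direction in cells and pools was 79.7% (higher) and 97.4% (lower) with means of log2 values, and 85.8% and 89.2% in cells with Lmx1a. The cause was not tested for these values. No subthalamic lineage-like cluster was found at resolution 0.5, with 10 neighbours or among cells with at least 4000 genes, and no dopamine neuron-like cluster at resolution 0.5, so these gave no values. Of shares of cells with a listed gene 2533 of 2926 stayed within their interval, and of other single-cell values 1979 of 2160.

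No paired analysis was possible because the labels give the pools no shared replicate numbers. Alternatives that need read counts, including thinning cells to 1 depth, were not run, as the tables hold no counts. An RPKM of 10 for a 2 kb transcript is about 27.2 reads in a median cell, so levels near an RPKM of 1 rest on few reads.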

Other observations

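Both tests on genes per cell, with bounds on the ratio of medians, were planned before their results were seen. The condition that quartiles do not overlap was not part of that plan.

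In single cells Nr4a2 was more frequent than Th at later stages, at 40.4% (33.2 to 48.05) against 8.99% (5.23 to 14.2) at E12.5 and 42.8% (34.6 to 51.2) against 14.5% (9.19 to 21.3) at E13.5. The reporter transcript was found in 75.2% (67.1 to 82.2) of cells at E10.5 and 26.9% (19.9 to 34.9) at E13.5, while Lmx1a was found in 50.3% (41.9 to 58.7) at E13.5. Among guidance genes, the Slit ligand gene Slit2 and the netrin gene Ntn1 were higher in GFP positive pools at both stages (3.604 and 2.65; 2.04 and 2.21). Of red blood cell genes, Hba-a1 was found in 13, 8, 28 and 15 cells at the successive stages, Alas2 in 5, 3, 5 and 9, Hbb-y in 4, 0, 3 and 0, and each of the other 6 in at most 5 cells of a stage. Each of the 8 microglia and macrophage genes was found in 0 of 550 cells.

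More genes were detected per cell at E10.5 than at E13.5, with medians of 5747 and 4287. Deeper sequencing at E10.5 is argued against, since among cells of 1 to 2 M implied reads the ratio of medians was 1.56 (5941, quartiles 5180.0 to 6453, against 3806, quartiles 3147.5 to 4817.5). A larger share of cycling progenitors at E10.5 was also tested. Within progenitor-like clusters the ratio was 1.26 (22 cells at E13.5), and the quartiles overlapped (4313 to 6409 and 3479.5 to 4990.5). By the planned bound, which was on the ratio alone, this counts against a larger share of progenitors as the explanation. With the condition on quartiles, which was not planned, the test left that explanation undecided. This explanation and a difference between stages within progenitors cannot be told apart, because few E13.5 cells fell in these clusters and they are other clusters than at E10.5.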
